A study of Mus musculus with 2 samples.

How the data were processed

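MicroRNA-seq libraries from total RNA of 2 mouse livers at postnatal day 0 were used, replicate 1 from pup 1 and replicate 2 from pup 2 of the same litter, per the labels. The deposited values are raw read counts per microRNA gene, 1 file per library, on assembly mm10 with GENCODE annotation M4, per the text deposited with the files. The aligner, the counting program, adapter trimming and mismatch limits are not given in the sources used here. Each file holds counts made without regard to strand, counts on the strand of the gene and counts on the opposite strand. These columns have no header, and their meaning was taken from the values: the leading entries for unassigned reads plus the gene counts add up to the same number of uniquely mapped reads in each column. Counts on the gene strand were the main values. Reads that mapped to several loci are given as a total only and are on no gene, so genes with near-identical copies are undercounted by an unknown amount. Each gene entry covers a whole hairpin, so the arms of a microRNA are not told apart. Levels of different microRNAs were not corrected for differences in ligation or capture between sequences.

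Of all reads, 12.5% were unmapped and 25.2% mapped to several loci in replicate 1, and 14.4% and 24.7% in replicate 2. Gene-strand microRNA counts made up 91.1% and 90.1% of uniquely mapped reads, and opposite-strand counts 4.44% and 4.25%. Uniquely mapped reads outside microRNA genes on the gene strand numbered 333144 and 499994 and stayed out of library sizes and tests. Gene symbols, coordinates, host genes and hairpin sequences came from GENCODE M21 on the same assembly. Of 1973 gene identifiers, 1894 had a symbol there, and the 79 without a symbol held 0 counts. A hairpin that shares a stretch of 20 bases with the hairpin of another microRNA locus, on either strand, was marked as uncertain. Loci that overlap the hairpin were left out of this check.

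Counts were divided by the library's total of gene-strand microRNA counts and multiplied by 1000000 (CPM). Means and SDs are over 2 pups. Shares of counts per library have exact Clopper-Pearson 95% intervals, and the limit for a count of 0 is 3 counts of the library total. Detection meant at least 10 counts in both libraries. Correlations across genes used log2(CPM + 1). Genes with at least 10 counts over both libraries were compared between the pups with a two-sided exact binomial test conditional on the gene's total and the library sizes, with Benjamini-Hochberg adjustment at 0.05 over 390 genes. The common dispersion was estimated with edgeR from an intercept-only design, and the negative binomial exact test of edgeR used it as an alternative. A quasi-likelihood test between groups was not possible, because the series used here has no second group. The median log2 ratio of each gene set was placed among 10000 random sets of the same size matched on mean expression in 10 bins, which describes these libraries and is not a test of a condition. Positive log2 ratios mean higher in replicate 2.

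The 18 gene sets hold 166 genes, of which 12 had no entry in the table. These sets and the rule for naming genes were fixed before the data were examined. So were the tests and the alternatives, apart from those listed next. The tests of what might explain the Mir206 difference and the test of blood cells were chosen only after the results were seen. The same holds for the sum without Mir133b, the interval for GC content, the pairing of opposite-strand reads with genes and 3 of the alternatives. Named genes were the 15 with the highest mean CPM, up to 4 of the highest members of each set, and, among genes with at least 100 counts in both libraries that passed the binomial test, the 5 highest and the 5 lowest log2 ratios. Other genes are named only where they are exceptions to a count or were picked after their values were seen: Mir669f, Mir133b, Mir150, Mir30c-2, Mir15a, Mir99b, Mir541, Mir337, Mir376c, Mir494, Mir1197, Mir432, Mir654, the genes read on the opposite strand, the clusters named as exceptions and the further genes in the closing observations. Alternatives were counts without strand, TMM and DESeq2 size factors, other filters on low counts, a pseudocount of 10, leaving out Mir122, leaving out the genes marked as uncertain, each pup alone, and 3 alternatives added after the data were seen.

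The comparison was tested on simulated data with counting error only, drawn from the means and library sizes of the real genes. In these data 200 genes outside the 50 most abundant were changed. Library sizes were taken from the unchanged genes, which the real comparison did not know. The binomial test then recovered 52.0% of genes changed 1.25-fold, 74.0% at 1.5-fold, 66.0% at 2-fold and 88.0% at 4-fold. Genes too weak to be tested count as missed. With these library sizes the test called 4 of 193 unchanged genes. With total counts, as in the real comparison, it called 28, because the simulated changes moved the totals. In a simulation without change and with counting error only, the binomial test called 0 of 389 genes. In a separate simulation without change, with a coefficient of variation of 0.100 between libraries, the negative binomial test of edgeR called 0 genes. The binomial test was not run on simulated counts with such spread, so its calls under spread between pups were not checked. A coefficient of variation simulated as 0.100 was estimated as 0.111. R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. Alignment files and reads were not used here.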

Results

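MicroRNA sequencing was carried out on total RNA from the livers of 2 newborn mouse pups of strain B6NCrl at postnatal day 0, with inserts selected below 30 bases. Both pups came from the same pregnant female, and their sex was not recorded. Each liver gave 1 library, so the data form 1 group of 2 biological replicates with no treatment, second tissue or second age to set against it. Replicate 1 held 6028986 reads, of which 3755766 mapped to a single locus and 3422622 were counted on the strand of a microRNA gene. Replicate 2 held 8277738 reads, with 5038421 mapped to a single locus and 4538427 counted on the strand of a microRNA gene. All levels are counts per 1000000 of these microRNA counts (CPM), with the mean ± SD over n = 2 pups. A gene at 0 counts could have had up to 0.877 CPM in replicate 1 and 0.661 CPM in replicate 2, the limits that a count of 0 allows. These limits and all intervals are at 95% and cover counting error only, since reads copied by PCR are not independent molecules. An exact sign-flip permutation test over 2 pups cannot give a two-sided p below 0.5, so comparisons between genes rest on sizes and on the spread between the pups.

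The first question was which microRNAs the newborn liver contained and at what level. In uniquely mapped reads of the genes in the table, Mir122 was by far the most abundant, followed by Mir126a, Mirlet7g, Mir26b and Mir21a. Mir22, Mir335, Mir411, Mir101b and Mir99a completed the 10 highest genes, and the same 10 genes led in both pups. Mir122 (ENSMUSG00000065402.1; chromosome 18, 65248861 to 65248926, plus strand, mm10) stood at 348624 ± 8931 CPM. It took 34.2% of the microRNA counts in replicate 1 and 35.5% in replicate 2, a mean of 34.9% ± 0.893. Mir126a, which overlaps an exon of an annotated Egfl7 transcript on chromosome 2 (26591357 to 26591429), reached 67576 ± 2260 CPM. Other transcripts of Egfl7 may hold it in an intron. The Mir122 level was 5.16 ± 0.0404 times that of Mir126a, a gap far larger than the spread between the pups. Mirlet7g, in an intron of Wdr82 on chromosome 9 (106178840 to 106178927), stood at 41287 ± 223 CPM, and the Mir126a level was 1.64 ± 0.0636 times that. Mir26b in an intron of Ctdsp1 had 39047 ± 2984 CPM, Mir21a at Vmp1 had 32837 ± 4096 CPM and Mir22 at its host transcript Mir22hg had 27131 ± 1416 CPM. Mir335, in an intron of the imprinted gene Mest on chromosome 6 (30741299 to 30741396), had 22369 ± 1933 CPM. Levels of Mir101b, Mir411 and Mir23b count as uncertain, because each shares a stretch of 20 bases with 1 other microRNA locus. The order of genes closer together than their SDs, such as Mirlet7g and Mir26b, was not resolved. Reads at several loci, 25.2% of all reads in replicate 1 and 24.7% in replicate 2, are on no gene. Genes with near-identical copies can therefore be missing from this order, and the shares of counts leave those reads out. Mir142, which has no entry, had 13061 CPM of reads at its place, above Mir23b at 12518.5 CPM.

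The 10 highest genes together held 63.4% ± 0.504 of the microRNA counts and the 100 highest held 97.6% ± 0.0457. At least 10 counts in both libraries were found for 312 of the 1973 microRNA genes in the table. A further 1317 genes were at 0 in both libraries. The next levels, from the gene ranked 10 by mean, were Mir99a (17268 ± 209 CPM), Mirlet7i (15528 ± 1492 CPM), Mir30a (15294 ± 2206 CPM), Mir322 (14275 ± 339 CPM) and Mir143 (14225 ± 555 CPM). Replicate 2 had Mir431 among its 15 highest genes where replicate 1 had Mir30e, and the other 14 were shared.

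**Figure D1:**
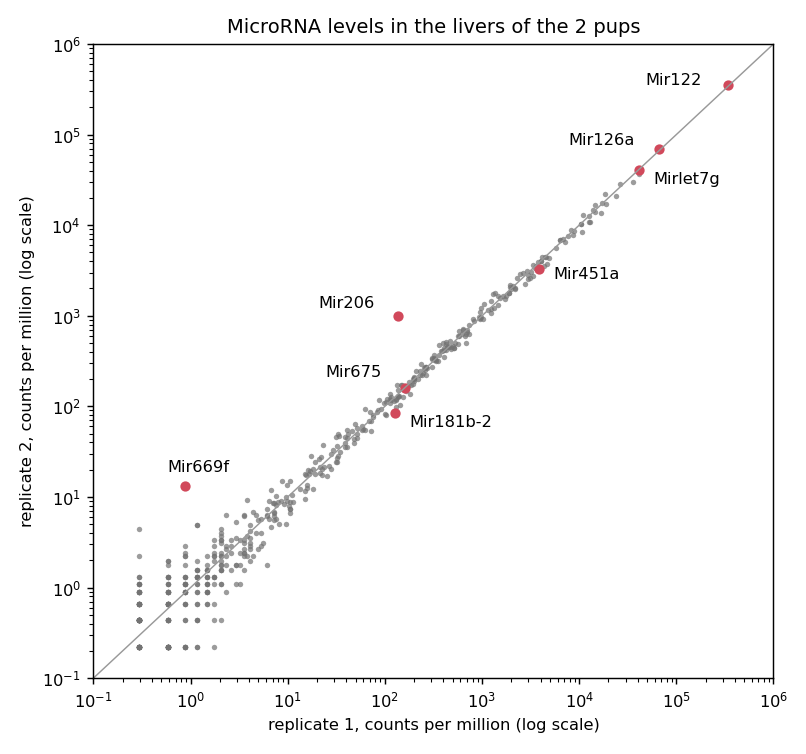
Level of each microRNA gene with a count in both libraries, in CPM on log scales, for replicate 1 (horizontal) and replicate 2 (vertical); each point is a gene and the line marks equal levels. Mir122 is highest in both pups, and Mir206 and Mir669f lie far above the line.

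The next question was how the microRNA pool divided among sets of genes known from particular cell types, families or clusters. In uniquely mapped reads, the liver-enriched set came first, the Dlk1-Dio3 imprinted cluster came next, and the let-7 family and endothelial Mir126a followed. Sets typical of blood cells, of epithelia, of the pancreas, of muscle and of neurons held small shares, with Mir142 missing from the leukocyte set. Liver-enriched genes held 36.4% ± 0.825 of the counts, and Mir122 alone made up 95.8% ± 0.281 of that set. The other liver-enriched genes were led by Mir192 (8746 ± 118 CPM), Mir148a (3500 ± 275 CPM) and Mir194-2 (2733 ± 295 CPM). The Mir192 level was 3.22 ± 0.304 times that of its neighbour Mir194-2 on chromosome 19, although Mir194-2 has a near-identical copy and its count is uncertain. The let-7 family held 6.97% ± 0.179, of which Mirlet7g made up 59.2% ± 1.84. Of its genes in the table, 5 of 10 share a stretch of 20 bases with another locus, and 2 more have no entry. Reads at several loci were not counted, so the place of let-7 against the Dlk1-Dio3 cluster and Mir126a is not settled. Mir126a held 6.76% ± 0.226, which was not separated from the let-7 family.

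Genes of the Mir30 family held 3.21% ± 0.405, led by Mir30a and Mir30e (11799 ± 1471 CPM). The Mir17 cluster and its paralogous clusters held 2.61% ± 0.298, led by Mir17 (9573 ± 1516 CPM) and Mir20a (4200 ± 675 CPM), and were not separated from the Mir30 family. Mesenchymal genes held 1.54% ± 0.0559, with Mir143 making up 92.3% ± 0.254 of them and Mir214 at 700 ± 3.33 CPM. Leukocyte genes held 0.995% ± 0.0626, led among the genes in the table by Mir223 (8207 ± 510 CPM), Mir342 (1166 ± 119 CPM), Mir146 (422 ± 2.86 CPM) and Mir155 (112 ± 3.50 CPM). This leukocyte share leaves out Mir142, which has no entry of its own in the table. Erythroid genes held 0.523% ± 0.0112, with Mir451a (chromosome 11, 78073170 to 78073241) at 3593 ± 401 CPM, its neighbour Mir144 at 1580 ± 291 CPM and Mir486 at 56.0 ± 2.22 CPM. The erythroid gene Mir486b has no entry in the table. Mir486 overlaps Mir3107 on the opposite strand, and overlapping loci were left out of the check for shared sequence. The Mir486 level, the erythroid share and ratios to that share are therefore uncertain, and the level and share may be too low. The liver-enriched share was 69.6 ± 3.07 times the erythroid share and 36.6 ± 3.13 times the leukocyte share, or 15.8 ± 0.992 times the leukocyte share once reads at the place of Mir142 and of other genes without an entry were added.

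The epithelial Mir200 family held 0.675% ± 0.0133, led by Mir429 (4491 ± 130 CPM) and Mir200b (1634 ± 6.16 CPM). Genes of the Hox clusters held 0.371% ± 0.00409, with Mir10a at 3422 ± 79.4 CPM and Mir10b at 153 ± 26.4 CPM, a ratio of 22.8 ± 4.45. Pancreatic genes held 0.204% ± 0.0119, and Mir375 (2004 ± 113 CPM) made up 98.4% ± 0.209 of them. The Mir183 cluster held 0.138% ± 0.00431, led by Mir182 (660 ± 35.7 CPM), and the Mir29 family held 0.0780% ± 0.00744, led by Mir29a (682 ± 63.3 CPM). Muscle genes held 0.0181% in replicate 1 and 0.107% in replicate 2, a spread set by Mir206. Neural genes held 0.0144% ± 0.00101, led by Mir128-1 (88.4 ± 5.21 CPM) and Mir137 (18.2 ± 1.73 CPM). Pluripotent genes held 0.0115% ± 0.000127, led by Mir294 (42.6 ± 5.24 CPM) and Mir293 (27.8 ± 5.33 CPM). Neural and muscle totals are uncertain, since 13 of 15 neural and 4 of 8 muscle genes in the table share a stretch of 20 bases with another locus, and without such genes the neural share was 0.00192%. Of the 153 pairs of sets, 148 differed in that the values of the pups did not overlap and the gap exceeded the sum of the SDs. The muscle set accounted for 3 of the 5 pairs that were not separated, with the Mir29 family, the neural set and the pluripotent set.

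**Figure D2:**
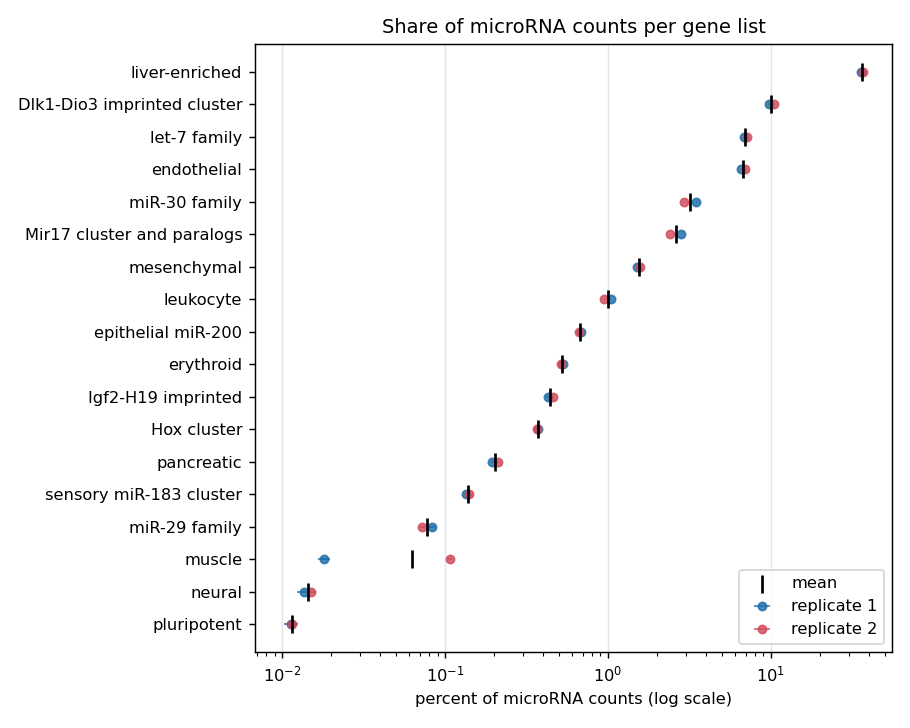
Percent of microRNA counts, on a log scale, held by each of 18 gene sets in replicate 1 and replicate 2, with exact binomial 95% intervals that are mostly narrower than the points, and the mean as a vertical bar. Liver-enriched genes hold 36.4% on average, and the pups lie far apart for the muscle set, at 0.0181% and 0.107%.

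Imprinted microRNAs were abundant at this age. In uniquely mapped reads, the Dlk1-Dio3 cluster on chromosome 12 held the largest share after the liver-enriched set, although its place above the let-7 family is not settled. Its genes were expressed along the whole region, led by Mir411, Mir431, Mir127 and Mir379. The Igf2-H19 pair, Mir483 and Mir675, was expressed too, with Mir483 far above Mir675. The Dlk1-Dio3 genes in the table lie between 109563692 and 109747960 on chromosome 12 and held 10.1% ± 0.553 of the counts, or 7.19% without the genes that share 20 bases with another locus, such as Mir411. Of these 44 genes, 41 had at least 10 counts in both libraries and 16 had a mean of at least 1000 CPM. The exceptions were Mir1197, with 3 and 11 counts, and Mir432 and Mir654, at 0 in both libraries. Mir411 stood at 20319 ± 2787 CPM, Mir431 at 11840 ± 1440 CPM, Mir127 at 10444 ± 79.5 CPM and Mir379 at 8552 ± 346 CPM. Mir770, in an exon of Meg3 at the left end of the region, had 40.6 ± 9.89 CPM. The liver-enriched share was 3.61 ± 0.117 times the Dlk1-Dio3 share. Mir483, in an intron of Igf2 on chromosome 7 (142654924 to 142654996), had 4268 ± 235 CPM and Mir675, in an exon of H19, had 160 ± 0.153 CPM. Their ratio was 26.6 ± 1.49, and together they held 0.443% ± 0.0234 of the counts.

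**Figure D3:**
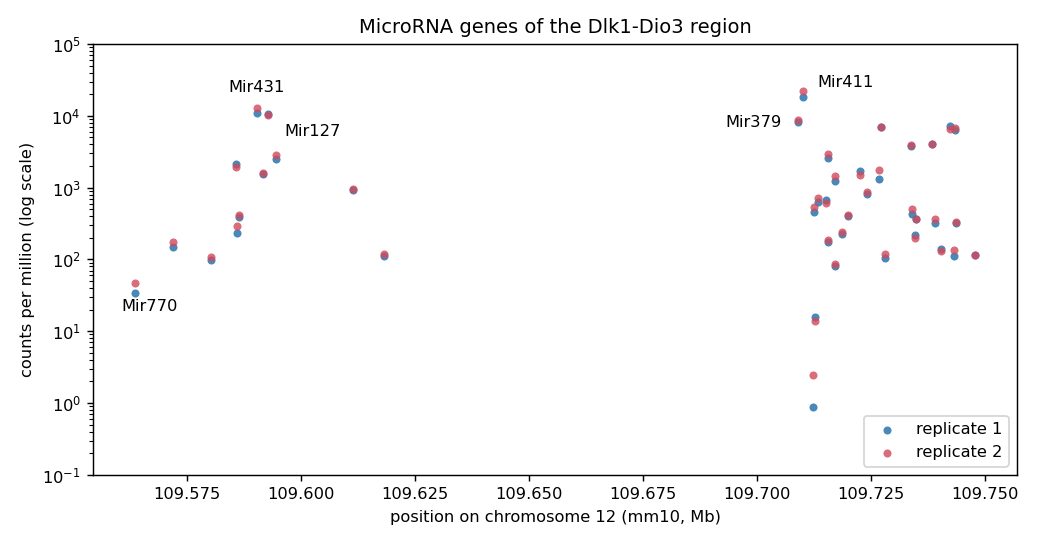
Level in CPM (log scale) of the microRNA genes of the Dlk1-Dio3 region against their position on chromosome 12 (mm10), for replicate 1 and replicate 2; genes at 0 counts are not drawn. Genes on both sides of the gap in the middle of the region reach levels near or above 10000 CPM, such as Mir431, Mir127 and Mir411.

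The livers of the 2 pups were then compared to measure how closely replicates matched. The profiles were close for well-counted genes, from Mir122 and Mir126a down to Mir675, and scattered more among weakly expressed genes such as Mir669f. Across the 656 genes with a count in either library, log2(CPM + 1) had a Pearson correlation of 0.995 and a Spearman correlation of 0.940, and the Spearman correlation was 0.994 over genes with at least 10 counts in both libraries. These are correlations across genes, which are not independent replicates. The common biological coefficient of variation estimated by edgeR over 390 genes was 0.130. Among the 221 genes with at least 100 counts in both libraries, 219 lay within 1.5-fold of each other, and the median size of the log2 ratio was 0.12. The exceptions were Mir206 and Mir181b-2. Mir15a, Mir675, Mir99b and Mir23b, picked after their values were seen, were nearly equal in the pups, with log2 ratios of 0.00 for each. A chi-square test of the counts over genes gave 19424 on 389 degrees of freedom, or 49.9 per degree of freedom, so the libraries differed by more than counting error and were not the same library deposited under another name.

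Individual genes were compared between the pups to find where the livers differed. Mir206 was the clearest difference, far higher in replicate 2. Small shifts were frequent among abundant genes: Mir411, Mirlet7i and Mir144 were higher in replicate 2, and Mir21a, Mir30a, Mir17 and Mir20a were lower. The test used on each gene asks only whether the difference exceeds counting error between these libraries. It says nothing of a difference between conditions. With the exact binomial test and Benjamini-Hochberg adjustment, 118 of 390 genes differed, 62 higher and 56 lower in replicate 2. Only 8 of the 118 differed by more than 2-fold. Mir206 (ENSMUSG00000065559.1; chromosome 1, 20679010 to 20679082) had 466 counts in replicate 1 and 4555 in replicate 2, or 136 and 1004 CPM. Its log2 ratio was 2.88 (exact 95% interval 2.74 to 3.02), a 7.37-fold difference, and its mean level of 570 ± 613 CPM therefore describes neither pup.

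When the spread between the pups was taken as noise, in the negative binomial exact test of edgeR with the common dispersion, 2 of the 390 genes were called. They were Mir206 and Mir669f. The dispersion came from the same 2 libraries, 1 per pup, so these differences have no replicate check and describe the libraries only. Mir669f, which was not among the genes picked by the fixed rule and was named after its values were seen, lies in an intron of Sfmbt2 and had 3 and 60 counts, a log2 ratio of 3.91 (2.30 to 6.23). It shares sequence with 44 other loci, so its count is uncertain. Among genes with at least 100 counts in both libraries that passed the binomial test, the highest log2 ratios after Mir206 were those of Mir6236 (0.57), Mir700 (0.57), Mir125b-1 (0.57) and Mir770 (0.50). The lowest were those of Mir181b-2 (-0.60), Mirlet7a-2 (-0.47), Mir16-2 (-0.45), Mir362 (-0.43) and Mir106a (-0.42). Mir125b-1, Mir181b-2, Mirlet7a-2 and Mir16-2 share sequence with other loci and are uncertain. Among abundant genes, the log2 ratio was 0.05 for Mir122, 0.07 for Mir126a, -0.01 for Mirlet7g, -0.26 for Mir21a, -0.30 for Mir30a and 0.28 for Mir411. Mir144 had a log2 ratio of 0.38 and its neighbour Mir451a had -0.23, so the ratio of Mir451a to Mir144 was 2.82 in replicate 1 and 1.85 in replicate 2. Neither gene was called by the negative binomial test.

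The gene sets were compared between the pups in the same way. Muscle genes and Dlk1-Dio3 genes lay higher in replicate 2 than random sets of equal abundance, and the genes of the Mir17 cluster and its paralogs leaned lower. The random sets were drawn gene by gene, whereas the Dlk1-Dio3 genes lie within 184 kb and the Mir17 genes in a few clusters. Neighbouring genes may shift together, so percentiles can overstate how unusual such sets were. For liver-enriched, let-7, blood cell and epithelial genes the median of the set lay among those of random sets, while their shares of counts differed by more than counting error. The median log2 ratio of the muscle set was 0.72, at percentile 99.9 of 10000 random sets of the same size matched on mean expression. Of its 5 genes tested, Mir206, Mir133b and Mir208b were higher, and 1 of them, Mir206, passed the negative binomial test. Without Mir206 the muscle median was 0.52, at percentile 96.7, so its place outside the central 95% rested on that gene. The Dlk1-Dio3 median was 0.09, at percentile 99.9, with 17 of 42 genes higher and 4 lower, namely Mir541, Mir337, Mir376c and Mir494, and 0 called by the negative binomial test. Genes of this region without an entry are not among the 42. Reads at the places of Mir376a and Mir409 fell from 9359 to 8567 CPM and from 8179 to 7567 CPM in replicate 2. Those at the place of Mir299a rose from 2883 to 3144 CPM, and those of Mir380 were nearly equal, at 1516 and 1528 CPM. The Mir17 cluster and its paralogs had a median of -0.14, at percentile 4.26, with 0 of 15 genes higher and 8 lower by the exact binomial test and 0 called by the negative binomial test. The Mir17 share fell from 2.82% to 2.40%. The Mir30 share fell as well, from 3.49% to 2.92%, with 3 of its 6 genes lower, Mir30a, Mir30e and Mir30d, and Mir30c-2 higher, so its median of -0.04 does not show the fall. The leukocyte share went from 1.04% to 0.951% and the liver-enriched share from 35.8% to 37.0%, with exact binomial intervals that did not overlap.

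The medians of the other sets lay within the central 95% of their random sets. The liver-enriched median was -0.08 (percentile 25.6), the erythroid median -0.08 (34.2), the leukocyte median -0.06 (28.7), the mesenchymal median -0.01 (51.6) and the Mir200 median -0.06 (22.2). The let-7 median was 0.00 (60.7), the Hox median 0.25 (97.2), the Mir29 median -0.03 (43.8) and the Mir30 median -0.04 (36.6). The neural median was 0.19 (89.1), the pancreatic median 0.40 (96.0), the Mir183 median 0.08 (76.2) and the pluripotent median -0.13 (29.5). In all, 2 of 16 sets lay outside that range, and with counts made without strand the Hox set (98.0) and the pancreatic set (97.6) lay outside it too. Adjusted over the list alone, the Dlk1-Dio3 set again had 17 genes higher and 4 lower, the Mir17 set 0 higher and 8 lower, and the muscle set 3 higher. Liver-enriched genes went from 1 to 2 higher, let-7 genes from 3 to 4 lower and Hox genes from 1 to 2 higher when adjusted over the list alone, and the counts of the other sets stayed as over all genes tested.

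**Figure D4:**
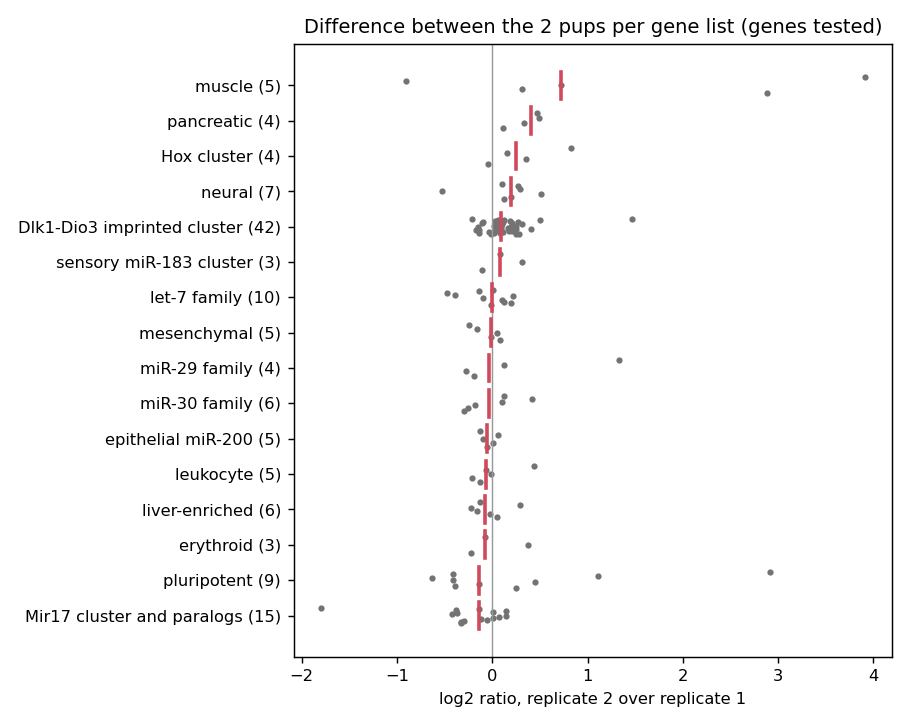
Log2 ratio of replicate 2 over replicate 1 for each gene tested in the 16 sets with at least 3 such genes, as points, with the median of each set as a vertical bar and the number of genes tested in parentheses. The muscle median lies at 0.72 and the Dlk1-Dio3 median at 0.09, while that of the Mir17 cluster and its paralogs lies at -0.14.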

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

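The tests on reads shared between loci were chosen before their results were seen, and the pairing of opposite-strand reads with genes was made only after those reads were seen. Reads on the strand opposite to a gene were not part of any comparison, and at 20 genes they were above the limit that a count of 0 allows in both libraries. At 10 of these they had at least 100 counts and outnumbered the gene-strand counts in both libraries. At each of those 10, the annotation places another microRNA on the strand the reads came from, and that microRNA has no entry in the table. The highest was the place of Mir142, a leukocyte microRNA, where opposite-strand reads at Mir142b averaged 13061 ± 296 CPM, on the scale of the gene-strand total, above Mir223 at 8207 ± 510. The places of Mir376a, at Gm25252, and Mir409, at Gm24321, both in the Dlk1-Dio3 region, had 8963 ± 561 and 7873 ± 433 CPM. Reads at the place of Mir378a (Gm25301) averaged 6761 ± 142 and those at the place of Mir191 (Gm24083) averaged 4160 ± 76.4 CPM. Mir299a, read at Mir299b, had 3014 ± 184, Mirlet7e, read at Gm25927, had 2149 ± 50.9, and Mir380, read at Gm25750, had 1522 ± 8.83 CPM. Mir497, read at Mir497b, had 168 ± 12.6 and Mirlet7f-1, read at Gm24111, had 73.3 ± 6.19 CPM. At the other 10 genes, opposite-strand reads were about as many at Mir203 (70.3 ± 1.33 CPM) as at the last of these places, but fewer than its own gene-strand reads. The remaining values were those at Mir126a (28.4 ± 4.91), Mir3074-1 (26.5 ± 3.83), Mir337 (12.3 ± 1.20), Mir129-2 (8.64 ± 1.00, also above its gene-strand counts), Mir486 (5.24 ± 0.860), Mir130a (4.03 ± 2.40), Mir292 (3.88 ± 0.119), Mir183 (1.87 ± 1.08) and Mir122 (1.61 ± 0.213). The 10 highest places held 99.6% of all opposite-strand counts in each library. Adding the reads at the 10 highest places to the sets of their genes raised the leukocyte share from 0.995% to 2.20% ± 0.0857 and the Dlk1-Dio3 share from 10.1% to 11.7% ± 0.464, while the let-7 share went from 6.97% to 6.87% ± 0.173 because the total grew too.

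Reads that mapped to several loci were the other signal outside the comparisons, at 25.2% of all reads in replicate 1 and 24.7% in replicate 2. Many genes that share 20 bases with another microRNA locus had low counts. In the let-7 family, Mirlet7a-1 stood at 159 ± 29.9 CPM against 41287 ± 223 for Mirlet7g, and the median of such let-7 genes was 124 CPM against 6653 CPM for the other let-7 genes. In the Dlk1-Dio3 set the order was the opposite, with a median of 4274 CPM for 4 sharing genes, Mir411 among them, against 406 CPM for 40 others. In 23 clusters of neighbouring microRNA genes that hold both kinds, the Poisson intervals of the kinds did not overlap in 95.7%, so the gaps exceeded counting error. At the high counts of most of these clusters, unlike genes are likely to differ that much whether or not they share sequence. The intervals were apart in 18 clusters in which the sharing genes were lower and 4 in which they were higher. This result therefore does not tell why sharing genes are low. The sharing genes had the lower median count in 82.6% of the clusters (19 of 23, exact two-sided sign test p 0.0026), and uncounted reads at several loci are a candidate explanation. The sign test takes clusters as independent. Sharing genes of some clusters are copies of each other, such as Mir16-1 and Mir16-2, so this p can overstate the evidence. The exceptions were the clusters of Mir194-1, Mir26a-2, Mir199b and Mir379, the last with the abundant sharing gene Mir411. Unequal processing of hairpins in a cluster was not tested and stays open, and the design gives no second group in which a biological explanation was tested.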

How the results depend on the processing

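Mir122 remained the most abundant gene and the liver-enriched set the largest in each pup alone and with counts without strand. The alternatives per uniquely mapped reads, with opposite-strand reads, and muscle without Mir206 were chosen only after the data were seen. With each pup alone, the Mir122 level ranged from 342309 to 354939 CPM, its share from 34.2% to 35.5%, the share of the 10 highest genes from 63.1% to 63.8%, the liver-enriched share from 35.8% to 37.0%, and detected genes from 320 to 343. Without strand, the totals include the opposite-strand reads, so the Mir122 level went from 348624 to 332689 CPM and its share to 33.3%, the share of the 10 highest genes to 60.5% and the liver-enriched share to 34.7%. That share was 34.7% too with opposite-strand reads added for genes without an entry, and 2.32% without Mir122. Without the genes that share 20 bases with another locus, the neural share went from 0.0144% to 0.00192%, Dlk1-Dio3 from 10.1% to 7.19%, let-7 from 6.97% to 6.75%, Mir29 from 0.0780% to 0.0682% and pluripotent from 0.0115% to 0.00999%. Per 1000000 uniquely mapped reads, Mir122 stood at 315831. Detected genes went from 312 to 533 at 1 count in both libraries, by the lower bound. The Pearson correlation went from 0.995 to 0.998 with log2(CPM + 10) and to 0.996 over genes with at least 10 counts in both libraries, where the Spearman correlation went from 0.940 to 0.994, since weak genes weigh less or are left out. The count of genes that differed between the pups stayed between 112 and 123 under other scalings, no filter and no strand, but went from 118 to 2 (2 higher, 0 lower; 12 at an unadjusted p under 0.05) with the negative binomial test, because it takes the spread between pups as noise; of the 10 named genes called for their ratio, 9 were no longer past the threshold and Mir206 was. Sets outside the percentile range went from 2 to 4 without strand, where the Hox set reached 98.0 and the pancreatic set 97.6; the cause was not tested. Median log2 ratios near 0 changed sign: let-7 to 0.00 (0.00198) without strand and 0.00391 with TMM, mesenchymal to 0.018 over genes with at least 100 counts, with 1 gene fewer. The other scalings moved log2 ratios by 0.004 and -0.002. Without Mir206 the muscle median was 0.52, at percentile 96.7, inside the range. The Mir29 and pancreatic sets had too few genes with at least 100 counts for a median. Leaving out Mir122 gives no value for its own level, and a comparison of the pups cannot leave out either. Depth limits what can be said of genes under about 10 counts.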

Other observations

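The tests of Mir206 and of blood cells were chosen only after the results were seen, as were the sum without Mir133b and the interval for GC content, and the test of hairpin GC content itself was chosen before. Mir206 was 7.37-fold higher in replicate 2, with a log2 ratio of 2.88. Counting error is argued against, since the lower bound of its interval was 2.74, and so is scaling, which shifts all genes alike, since that bound stayed 2.74 above the median of the other tested genes. A candidate source is skeletal muscle tissue carried along with the replicate 2 liver. Mir133b, Mir208b and Mir499 as a sum were higher in replicate 2 by a log2 ratio of 0.60 (95% interval 0.30 to 0.91), far less than Mir206. The interval of Mir499 alone included 0. This sum was chosen after the values were seen and left out Mir208a, which was not higher (17 and 12 counts), so it is no independent support for that source. Most counts of the sum were those of Mir208b (59 and 129) and Mir499 (76 and 125). Mir133b, a neighbour of Mir206, had only 21 counts over both libraries. The ratio of Mir206 to Mir133b was 466 in replicate 1 and 228 in replicate 2. On these few counts, Mir133b was therefore higher in replicate 2 by a larger ratio than Mir206. Mir133b shares sequence with another locus and its count is uncertain. Without Mir133b the log2 ratio of the sum was 0.50 (0.20 to 0.82). The abundant muscle genes Mir1a and Mir133a have near-identical copies and could not be read, and the design gives no second group, so the source stays open.

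Dlk1-Dio3 genes lay higher and genes of the Mir17 cluster and its paralogs lower in replicate 2, a gap of 0.23 between the median log2 ratios. Among random sets of like abundance the Mir17 median, at percentile 4.26, lay within the central 95%, and the Dlk1-Dio3 median, at 99.9, was picked from 16 sets. After a fit on hairpin GC content and expression 109% of the gap was kept (0.25), but the 95% interval over resampled genes reached down to 28.3%, so GC content is not excluded. Fewer blood cells in the replicate 2 liver might lower the Mir17 genes. The erythroid and leukocyte genes had a joint median of -0.075 against all tested genes (95% interval -0.21 to 0.38). Of these 8 genes 6 were lower, such as Mir451a, Mir223 and Mir342, and 2, Mir144 and Mir150, were higher. The median is only narrowly past the bar set for this explanation, 0.5 of the -0.14 of the Mir17 genes. The leukocyte gene Mir142 has no entry and is not among the 8. Reads at its place were 13270.5 CPM in replicate 1 and 12852 CPM in replicate 2, a smaller fall than this median. Adding it could therefore leave the median short of the bar. The interval of the median also includes 0, so the explanation stays open. Neither pup is a control, and a difference in maturity between littermates was not tested.

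Several abundant genes belonged to none of the sets and were picked after their values were seen. Mir130a had 11637 ± 1297 CPM, Mir23a 10381 ± 55.6 CPM (uncertain, since it shares 20 bases with another locus), Mir99b in an intron of Spaca6 7595 ± 15.8 CPM and Mir139 in an intron of Pde2a 5621 ± 131 CPM. Mir15a, in an intron of Dleu2, had 4422 ± 0.496 CPM. Mir322 and Mir351, neighbours on chromosome X, had 14275 ± 339 and 2439 ± 225 CPM. Of the 312 detected genes, 88 overlapped an exon of any annotated transcript on the same strand and held 57.1% of the counts, Mir122 included. A gene placed among these can lie in an intron of other transcripts of its host. Another 126 lay only in introns of an annotated gene on the same strand and held 24.5%, and 98 lay between genes and held 18.4%.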
